A study of Mus musculus with 6 samples.

How the data were processed

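RNA from 6 BCR-ABL positive mouse cell lines was extracted and sequenced after TruSeq RNA library preparation, per the labels' protocols. The deposited table held counts per gene symbol, 1 column per library, with no normalization. Per the submitters' processing notes Trim Galore, STAR and DESeq2 were used with the GRCm38 build. Their versions and roles, the counting program, the annotation and the strand setting are not given in the sources used here, so reads of overlapping, antisense or near-identical genes could not be told apart. The table had 25965 rows for 25899 symbols. The 66 rows that repeat an earlier symbol were kept as separate rows. In 11635 rows all 6 libraries were at 0, the 13 mitochondrial gene rows were at 0 throughout, and 25 symbols had been turned into dates by spreadsheet software and were not named. Every column matched the title of 1 sample, and groups were taken from the labels.

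Total counts were 24108563, 19060127 and 20241765 in WT1, WT2 and WT3 and 17859519, 20175564 and 20415572 in KO1, KO2 and KO3. The CPM equal to 3 counts is given as a floor for reading low values, and values at 0 were not replaced. Locations were taken from RefSeq gene tables of GRCm38, in which 20633 symbols matched by current symbol and 2296 by an older synonym, while 2970 were not placed. GC content and transcript length came from the GENCODE annotation of the same build.

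Choices made before the data were examined were as follows. The main test was edgeR 4.0.16 in R 4.3.3: counts were scaled by TMM, genes kept by filterByExpr on genotype, and a quasi-likelihood F test fitted with robust dispersion estimates over all 6 libraries, with Benjamini-Hochberg adjusted p under 0.05 as the threshold, two-sided. Cdk6 was also tested by an exact permutation test of log2 CPM, without a prior count. Principal components, library correlations and list medians per library used log2 CPM with a prior count of 2. Gene lists, 23 pathway lists and 8 lists of cell type markers with 584 genes in all, were tested by camera in limma 3.58.1 with a preset inter-gene correlation of 0.01 against all other tested genes, for the 29 lists with at least 5 tested genes, with p adjusted over lists. Of the list genes 7 were matched through a synonym and 6 had no row. For each list the members past the gene test were counted over all genes and adjusted over the list alone. The genes to be named were Cdk6, then among genes past the edgeR test with a mean log2 CPM of at least 1, groups that do not overlap and a regular gene symbol the 12 with the largest rise and the 12 with the largest fall, then up to 4 members of each list with the smallest adjusted p. The second part named 0 genes, and the same rule was then applied to the DESeq2 calls, after the data had been seen. A gene that the rule names in one list is not reported here.

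Alternatives were RLE size factors, library totals alone, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of 1 CPM in 3 libraries, a fit without robust estimates, the replicate number as a block, and leaving out each library in turn. For lists they also included camera with an estimated correlation, fry, and camera on DESeq2 statistics. With an estimated correlation camera takes its degrees of freedom from the few libraries and not from the genes, so it has less power to call a list. List medians in DESeq2 took in every member with a fold change, also low-count members that the edgeR filter left out. Leaving out WT2 and KO2, also with an estimated correlation for lists, and DESeq2 without either or both, were added after the data had been seen. DESeq2 gave no adjusted p for 14753 rows, which were left out of its counts.

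WT and KO carry the same replicate numbers, so pairing was checked by the correlation, across genes, of each library's deviation from its group mean. It was 0.33 for WT1 and KO1, 0.64 for WT2 and KO2 and 0.46 for WT3 and KO3, each above the criterion of 0.1 set in advance. The numbers were treated as pairing the libraries only in the fit with a block and in counts over splits. The main fit had no block, and the permutation test did not use pairing. The labels do not say that a number marks a shared culture, and WT1 correlated more with KO3 (0.41) than with KO1, and KO1 more with WT3 (0.36) than with WT1. WT2 correlated with KO1 and KO3, and KO2 with WT1 and WT3, at -0.58 to -0.45. The criterion was thus met mainly because WT2 resembles KO2, and the pairs with numbers 1 and 3 are not told apart by it.

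Regions were sought after the data had been seen, as runs of at least 3 bins of 10 Mb with at least 10 genes each and a median log2 ratio of KO2 to the mean of WT1 and WT3 of at least 0.3 in size, over 9173 placed genes with a mean of at least 5 CPM and an offset of 0.5 CPM. Intervals came from 1000 bootstrap draws over genes, which are not independent replicates.

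The tests were checked on simulated data, drawn for the 10896 tested genes with 200 of them changed 1.5-, 2- or 4-fold. Means and totals came from the real libraries, and the spread of each gene was the one edgeR estimated over all of them, KO2 included. edgeR called 7.6%, 41.8% and 71.6% of these and 8 of 10696 unchanged genes. DESeq2 called 31.8%, 64.2% and 85.1% and 79 unchanged genes, and limma-voom 1.5%, 26.9% and 65.7% and 4. With the S phase list lowered 1.25-fold, camera called it in 20 of 20 draws and called 8 of 558 other lists. Each gene was drawn on its own, so list members were uncorrelated and no library stood apart. These draws therefore do not show how often camera wrongly calls a list with correlated members. In the real libraries the estimated correlation was 0.3 for the S phase list and 0.71 for the class I list. Data handling used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures used matplotlib 3.10.9.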

Results

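Transcript levels were measured by RNA sequencing in 6 mouse cell lines carrying BCR-ABL, the fusion kinase made from the Philadelphia chromosome. In 3 lines (KO1 to KO3) Cdk6, the gene for a cyclin D-dependent kinase of the G1 phase, had been targeted with Cas9 and clones grown from single cells. The other 3 lines (WT1 to WT3) had received a control plasmid. Per the labels, loss of the protein had been checked by Western blot. The lines expressed genes of early B cells at high levels in both groups. Pax5, a transcription factor of the B lineage, lay at 173.9 ± 9.507 CPM (read counts scaled by library total; mean ± SD, n = 3) in WT and 190.2 ± 5.154 in KO, and the surrogate light chain gene Igll1 at 1169 ± 29.56 and 1000 ± 308. Total counts ran from 17859519 in KO1 to 24108563 in WT1, so that 3 counts corresponded to between 0.124 and 0.168 CPM. Intervals and floors given here cover counting error or the spread between genes or libraries as stated, and sequenced fragments were not counted as separate molecules.

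Library KO2 stood apart from the other 5. The first principal component of log2 CPM held 67.9% of the variance and placed KO2 at 112.5, WT2 at 12.6 and the other 4 libraries between -38.4 and -28.3. The Pearson correlation of KO2 with the other libraries, across genes, ran from 0.845 with KO3 to 0.921 with WT2, whereas WT1 and WT3 correlated at 0.99. WT1 and WT3 still differed by more than counting noise (chi-square per gene 6.1), so they are not one library deposited under 2 names. This does not show that they came from separate cultures. Xist, the RNA that silences the second X chromosome in female cells, lay at 2.16 CPM in KO2, at 728 CPM in WT2 and between 988 and 1638 CPM in the other 4 libraries. The Y-linked genes Kdm5d and Uty were at or near 0 in every library. In KO2, Cdkn2a and Cdkn2b, which encode inhibitors of CDK4 and CDK6, had 1 and 0 counts. They lay at 23.3 to 54.7 CPM and 4.56 to 7.76 CPM in the other 5 libraries.

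Against the mean of WT1 and WT3, 4 long regions had shifted expression in KO2 (GRCm38 coordinates, genes of at least 5 mean CPM). The 106 genes on chromosome 13 from 11553099 to 49734267 had a median log2 ratio of -0.88 (95% bootstrap interval over genes -0.99 to -0.78). The 227 genes along chromosome 18, from 3266354 to 89131014, had a median of -0.58 (-0.63 to -0.53). Higher medians were found for 145 genes on chromosome 6 from 100228565 to 137837872, at 0.62 (0.54 to 0.75). The 156 genes on chromosome 13 from 62864753 to 119791477 were at 0.56 (0.49 to 0.62). KO1 and KO3 had medians between -0.04 and 0.06 in these regions. WT2 had medians of -0.23 and -0.18 in the pair of lower regions and of 0.07 and -0.01 in the pair of higher ones. Of 238 bins of 10 Mb over the genome, 26 were shifted by at least 0.3 in KO2 and 0 in each of WT2, KO1 and KO3. WT1 and WT3 form the reference and were not counted. The regions and the reference libraries were chosen after the data had been seen, and no test between groups was made on them.

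**Figure D1:**
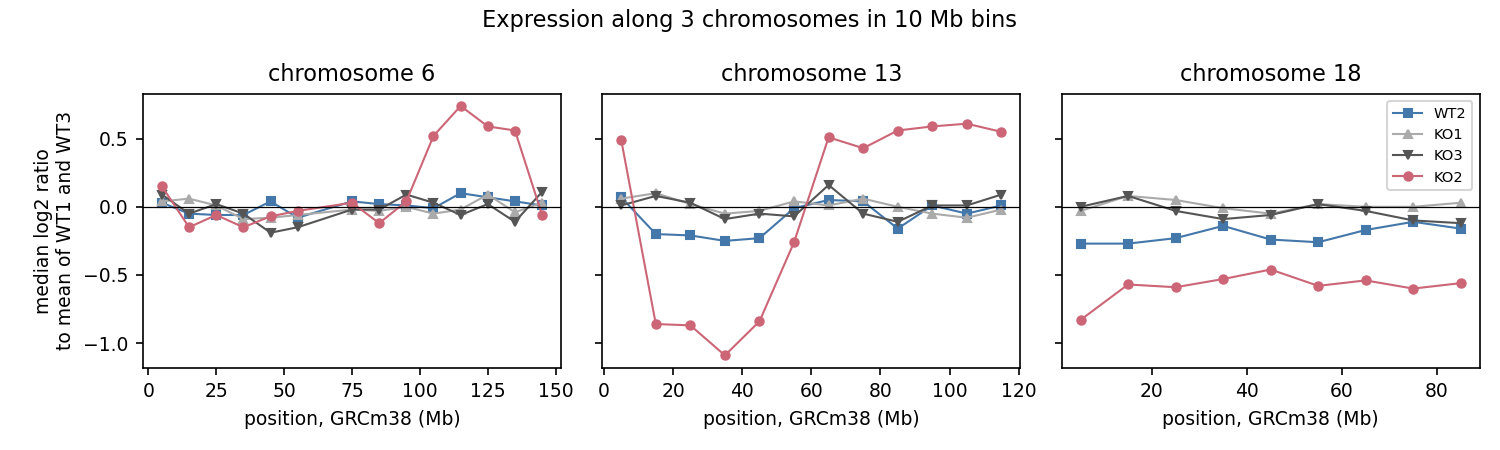
Median log2 ratio of expression to the mean of WT1 and WT3 (vertical axis) in bins of 10 Mb along chromosomes 6, 13 and 18 of GRCm38 (horizontal axis, Mb), with a line for each of WT2, KO1, KO2 and KO3. KO2 lies near -0.88 in the lower region of chromosome 13 and near -0.58 along chromosome 18, with WT2 between it and 0, while KO1 and KO3 stay near 0.

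The first comparison asked whether the targeted transcript was lower in the knockout lines. It was not: Cdk6 (chromosome 5, 3341004 to 3531008) lay at 39.7, 45.7 and 55.9 CPM in WT1, WT2 and WT3 and at 41.3, 75.2 and 39.0 CPM in KO1, KO2 and KO3. The means were 47.1 ± 8.19 CPM (SD, n = 3) in WT and 51.8 ± 20.3 CPM (SD, n = 3) in KO. The log2 fold change was 0.14 ± 0.29 (SE; 95% interval -0.59 to 0.86; edgeR adjusted p = 0.90). A two-sided exact permutation test gave p = 0.9, where 0.1 is the smallest p that 3 against 3 libraries allow. Without KO2 the log2 fold change was -0.22. Counts over a whole gene do not show a frameshift or a small deletion, so the RNA leaves the genotype open. KO and WT below name the libraries as labelled, including wherever a direction is given.

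Transcripts of the partners of CDK6 were measured beside it. Cdk4, the kinase closest to CDK6, lay at 733.8 ± 14.96 CPM in WT and 683.6 ± 39.3 CPM in KO (n = 3). Ccnd3, a D-type cyclin, lay at 1800 ± 135 and 2009 ± 181 CPM. Ccnd1 was at 414.6 to 445.2 CPM in the WT libraries, at 334.8 and 364.9 CPM in KO1 and KO3 and at 51.1 CPM in KO2. Ccnd2 was at 341.7 to 484.8 CPM in WT, at 418.3 and 484.9 CPM in KO1 and KO3 and at 1020 CPM in KO2, and it lies within the raised region of chromosome 6. None of the 23 tested genes for CDKs, cyclins, CDK inhibitors and pocket proteins passed the edgeR test, over all genes or adjusted over the list alone, or the DESeq2 test. Cdk4, the D-type cyclins, Cdkn2a, Cdkn2b, Pax5 and Igll1 were named after their values had been seen.

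**Figure D2:**
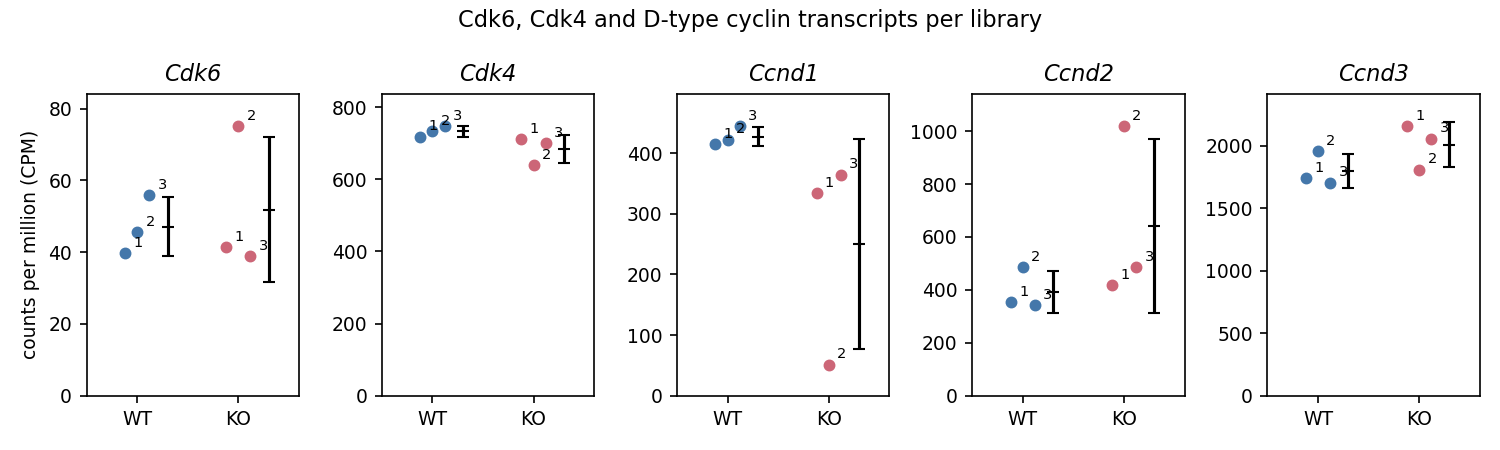
CPM (vertical axis, from 0) of Cdk6, Cdk4, Ccnd1, Ccnd2 and Ccnd3 in the WT and KO libraries, with a numbered point per library and a bar for mean ± SD (n = 3). Cdk6 overlaps between the groups, at 39.7 to 55.9 CPM in WT and 39.0 to 75.2 CPM in KO, and KO2 lies apart from KO1 and KO3 for Ccnd1 and Ccnd2.

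The second comparison asked which genes differed between KO and WT. By the test fixed in advance, edgeR's quasi-likelihood test on 10896 genes, 0 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.475. At an unadjusted p under 0.05 there were 1030 genes, where chance gives 545. That count changed with the libraries included: it was 408 without WT3, 472 without WT1 and 573 without WT2. It was 954 without KO3, 1234 without KO1 and 2080 without KO2. Leaving out a library also removes a replicate, so a lower count does not show that the excess rested on that library. limma-voom called 0 genes as well (1041 at an unadjusted p under 0.05), and DESeq2 called 218, of which 79 were higher and 139 lower in KO and 45 changed at least 2-fold. In 935 genes (8.6%) all KO libraries lay above all WT libraries and in 1200 (11%) all lay below, where chance gives 5% each way for libraries that are not paired. Taking both directions, 19.6% of genes separated the groups. The other 3 splits that part WT and KO of each number separated 4% to 6.3%, and the highest of all 9 other splits separated 16.8%. The genes were counted over splits after the groups had been compared.

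Among the genes called lower in KO by DESeq2, Mgat4a, a glycosyltransferase, had the smallest adjusted p: it lay at 68.8 ± 7.88 CPM in WT and 19.6 ± 3.78 CPM in KO (n = 3; log2 fold change -1.81 ± 0.20 SE, DESeq2 adjusted p = 7.4e-15). Cxcr3, a chemokine receptor, lay at 9.91 ± 2.61 and 0.339 ± 0.451 CPM (-4.85 ± 1.03, adjusted p = 0.000677). It was at 0.165, 0 and 0.851 CPM in KO1, KO2 and KO3. KO1 and KO2 thus lay at or under 3 counts, and the size of the fold change is uncertain. Lyz2, the lysozyme of myeloid cells, lay at 34.4 ± 6.31 and 14.2 ± 1.87 CPM (-1.27 ± 0.22, adjusted p = 1.15e-05). Marcks, a substrate of protein kinase C, was at 11.9, 1.07 and 21.6 CPM in WT1, WT2 and WT3 and at or under 0.494 CPM in the KO libraries. Ndrg1, Trem1, Rbm47, Hsd11b1, Ffar2, Adam33, St5 (now Denn2b) and Pnkd were the others among the 12 largest falls by the naming rule, with log2 fold changes from -1.97 (Adam33) to -1.14 (Pnkd).

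Among the rises, Mxd4, a MAX-binding repressor of the MYC network, lay at 26.5 ± 1.89 CPM in WT and 98.8 ± 32.0 CPM in KO (1.90 ± 0.27, DESeq2 adjusted p = 8.05e-09). Hes1, a transcriptional repressor downstream of Notch, lay at 0.555 ± 0.206 and 4.71 ± 1.95 CPM (3.08 ± 0.58, adjusted p = 5.62e-05). Ddit4, an inhibitor of mTORC1 signalling, lay at 19.3 ± 4.68 and 43.1 ± 9.89 CPM (1.17 ± 0.27, adjusted p = 0.00259). H2-Q7 and H2-Q6 had log2 fold changes of 3.04 ± 0.69 and 2.99 ± 0.82. As near copies of each other they may share reads. H2-Q6 lay at 1.085, 14.55 and 2.97 CPM in WT1, WT2 and WT3, so its DESeq2 value was 4.60 without WT2, and it was no longer called without KO2 (adjusted p = 0.162). Col6a6 (2.19, and 1.27 without WT2 and KO2), Otub2 (1.15), Zfp94 (1.03) and Pydc4 (now Ifi213; 0.98) followed, and so did Polk (0.99) and the paralogs Zfp874b (1.06) and Zfp874a (0.93), which lie within the raised region of chromosome 13 in KO2. Without WT2 and KO2 the DESeq2 values were 0.68 for Polk, 1.1 for Zfp874b and 0.76 for Zfp874a. Zfp874b was higher in KO3 (11.16 CPM) than in KO2 (8.469 CPM). The edgeR adjusted p of these 24 genes ran from 0.475 to 0.495. They were named by applying the rule to the DESeq2 calls after edgeR had called 0. Without WT2 and KO2 DESeq2 called 340 genes, 92 of them among the 218, all 92 in one direction in both fits. Of the 24 named genes 16 remained called. The other 8 were Zfp874b, Zfp94, Polk, Pydc4, Zfp874a, Adam33, Hsd11b1 and Ffar2. Without KO2 alone DESeq2 called 684 genes (185 of the 218 kept), and without WT2 alone 277 (168 kept). St5 lost its call without WT2 alone. On simulated counts with 200 changed genes, DESeq2 called 79 of 10696 unchanged genes and edgeR 8. DESeq2 called 21, 43 and 57 of the genes changed 1.5-, 2- and 4-fold, and edgeR 5, 28 and 48. Unchanged genes thus made up a far larger share of the simulated DESeq2 calls than its adjusted p threshold allows. Many of the 218 calls, and of the 24 genes named from them, may therefore be false. The simulated spread was the one edgeR estimated, and no library stood apart in the simulation, so it does not give the false share among the real calls. Of the genes changed 2-fold, edgeR recovered 41.8% and DESeq2 64.2%.

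The third comparison asked which of the gene lists fixed in advance moved as a whole. DNA replication genes driven by E2F were lower in KO: 24 of the 28 had a negative log2 fold change, with a median of -0.18, and in 16 of them all KO libraries lay below all WT libraries. Cdt1, which licenses replication origins, lay at 222.7 ± 3.20 CPM in WT and 165.1 ± 16.6 CPM in KO (log2 fold change -0.43 ± 0.09 SE, n = 3). Mcm2, of the replicative helicase, lay at 749.8 ± 32.5 and 600.3 ± 25.9 CPM (-0.32 ± 0.06). Gins1 (-0.38 ± 0.08) and Gins2 (-0.37 ± 0.08), also of the helicase, had similar values. Per library the median of the list, against the WT mean, was -0.20, -0.09 and -0.29 in KO1, KO2 and KO3 and between -0.04 and 0.05 in WT. Of the 28 genes 0 passed edgeR over all genes, 6 passed adjusted over the list alone, and 5 passed DESeq2. The list was called by camera with its preset correlation (adjusted p = 9.5e-09) and was not called with an estimated correlation (adjusted p = 0.416 with an estimated correlation).

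Genes of MYC and ribosome biogenesis were lower by less, with a median log2 fold change of -0.14 over 24 genes, 20 of them negative and 10 with all KO libraries below all WT libraries (camera adjusted p = 0.000219, and adjusted p = 0.416 with an estimated correlation). Cad, the enzyme that begins pyrimidine synthesis, lay at 748.3 ± 11.1 CPM in WT and 662.5 ± 23.1 CPM in KO (-0.18 ± 0.05). Nolc1 lay at 647.0 ± 10.6 and 579.0 ± 11.6 CPM (-0.16 ± 0.05), and Rrp9 and Mybbp1a had log2 fold changes of -0.27 and -0.19. No member passed edgeR, over all genes or adjusted over the list alone, and 1 passed DESeq2, Nolc1.

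MHC class I presentation genes were higher in KO, with positive log2 fold changes in 20 of 20 and a median of 0.57 (camera adjusted p = 9.25e-10, and adjusted p = 0.416 with an estimated correlation). H2-K1, a classical class I heavy chain, lay at 274.7 ± 28.3 CPM in WT and 408.1 ± 23.5 CPM in KO (0.57 ± 0.09), and H2-Q4 at 37.6 ± 5.17 and 67.6 ± 13.5 CPM (0.84 ± 0.18). Adjusted over the list alone 2 of the 20 genes passed edgeR, 0 passed over all genes and 4 passed DESeq2. The list did not separate the groups library by library: its median against the WT mean was 0.38 in WT2, 0.55 in KO1, 0.81 in KO2 and 0.05 in KO3. Without KO2 the median log2 fold change was 0.29 (camera adjusted p = 0.000442). Interferon-stimulated genes had a median of 0.91 over 18 genes, 17 of them positive (camera adjusted p = 2.67e-06, and adjusted p = 0.416 with an estimated correlation), which was 0.30 without KO2 and 0.36 without WT2 and KO2. Stat2 (0.45 ± 0.14), which carries the interferon signal, and the antiviral genes Oas3 (2.13 ± 0.50) and Oas1a (1.82 ± 0.61) were among the members with the smallest p-values. Oas3 did not pass the filter of 1 CPM in 3 libraries, so the size of its fold change is uncertain. With that filter the median of the list was 0.71 (camera adjusted p = 0.00114). Oas1a was at 0.96 without KO2, which held 11.65 CPM against 2.967 and 3.736 in KO1 and KO3. Of the members 0 passed edgeR, adjusted over the list alone or over all genes, or DESeq2.

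The p53 target genes had a median log2 fold change of 0.35 over 19 genes, 17 of them positive (camera adjusted p = 0.00808, and adjusted p = 0.416 with an estimated correlation). The size of this median depended on the tool and on the members included. Over the same libraries it was 0.15 in limma-voom and 0.18 with the replicate number as a block. In DESeq2, where low-count members were taken in, it was 0.24, and edgeR without the low-count filter gave 0.23. The list was called in limma-voom, with the block and in DESeq2. Zmat3, an RNA-binding protein induced by p53, lay at 28.6 ± 2.52 CPM in WT and 40.7 ± 1.98 CPM in KO (0.51 ± 0.10). Rrm2b, a ribonucleotide reductase subunit, lay at 20.1 ± 0.302 and 27.2 ± 2.52 CPM (0.44 ± 0.11). Bbc3 had a log2 fold change of 0.60 ± 0.27. Adjusted over the list alone 0 members passed edgeR, 0 passed over all genes and 3 passed DESeq2. The largest median was that of KO2, at 0.45, against 0.03 in KO1 and 0.19 in KO3. Without KO2 this list was no longer called (camera adjusted p = 0.068), and its median was 0.09. It was not called without the low-count filter either (adjusted p = 0.0549).

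**Figure D3:**
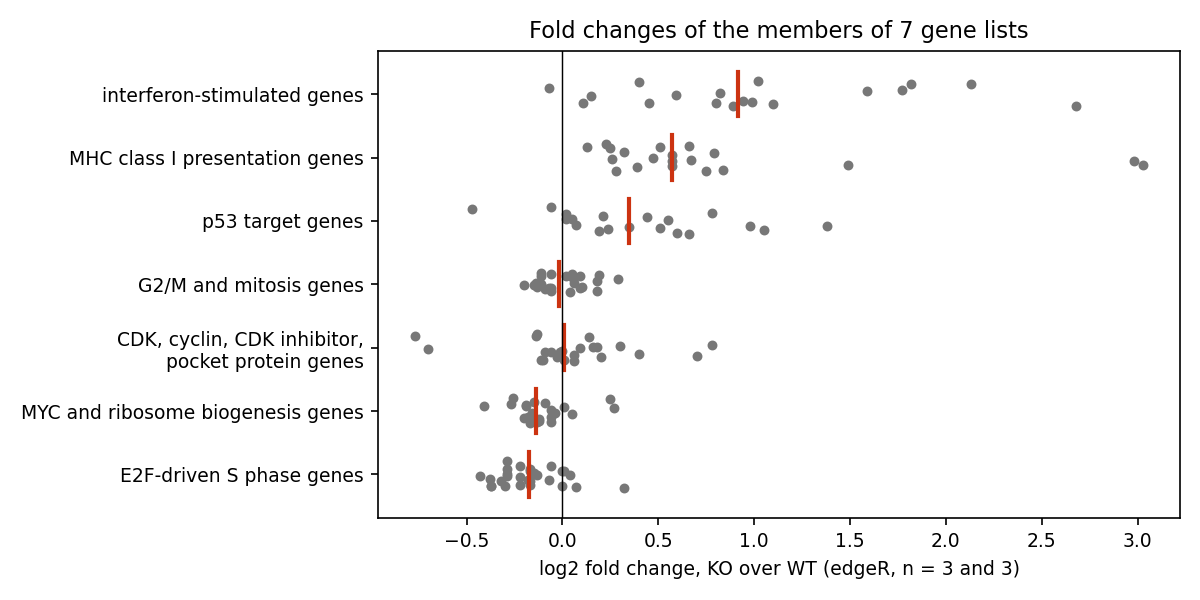
Log2 fold change, KO over WT (horizontal axis, edgeR, n = 3 and 3), of each tested member of 7 gene lists (rows), with a point per gene and a red line at the median. The 5 lists called by camera with a preset correlation have medians from -0.18 (E2F-driven S phase genes) to 0.91 (interferon-stimulated genes), and the CDK and cyclin list (0.01) and the G2/M list (-0.02) lie near 0.

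The remaining lists were not called, and the other 9 splits of the libraries into 3 and 3 called between 0 and 7 lists each. G2/M and mitosis genes had a median log2 fold change of -0.02 (camera adjusted p = 0.853), and without WT2 and KO2 they were called lower, at -0.08 (adjusted p = 0.00945), as were glycolysis genes, at -0.14 (0.0354). Leaving out KO2 alone also called both lower, at -0.09 (camera adjusted p = 0.00564) and -0.15 (0.00754). Leaving out WT2 alone called neither (0.983 and 0.293). The glycolysis median was 0 without KO1. With an estimated correlation neither was called, without WT2 and KO2 (adjusted p = 0.577 and 0.524) or over all libraries (adjusted p = 0.941 and 0.624). The camera direction of the G2/M list turned upward without WT2, KO1 or KO3. MHC class II presentation genes had a median of 0.43 (0.0503) and were called higher without WT2 and KO2, at 0.63 (0.00155), but not with an estimated correlation (adjusted p = 0.505, and 0.416 over all libraries). Their median in edgeR was 0.24 without KO2 or without WT3 and 0.73 without WT2, and they were called there without WT2 (0.0189) or KO2 (0.0441) alone. In DESeq2 they were called without WT2 (0.61, adjusted p = 0.000885) but not without KO2 (0.2, adjusted p = 0.192). Rfx5, a regulator of class II genes, lay at 25.9 CPM in WT and 44.8 CPM in KO. Several of the other medians rested on WT2 and KO2 and fell toward 0 without them.

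Over all libraries, and then without WT2 and KO2, the medians were 0.24 and -0.02 for BCL2 family genes, 0.31 and -0.01 for STAT5 targets, 0.21 and -0.07 for NF-kB targets and 0.22 and 0.05 for cytokine receptors. In the same order they were 0.42 and 0.20 for FOXO targets, 0.24 and 0.13 for Notch targets, 0.08 and 0.01 for genes tied to CDK6 in earlier work and -0.04 and 0.02 for cholesterol synthesis. For STAT5 targets the median of KO2 against the WT mean was 0.81, against 0.00 in KO1 and 0.01 in KO3. MAPK feedback genes, at 0.16 and 0.21, were called higher in edgeR without WT2 (0.25, camera adjusted p = 0.0189) or without KO1 (0.31, 0.0387) and in DESeq2 without WT2 (0.26, 0.0488). With an estimated correlation over all libraries they were not called (adjusted p = 0.416). Cytokine receptors were called in DESeq2 without WT2 (0.37, 0.0479), but not with an estimated correlation over all libraries (adjusted p = 0.416) or without WT2 and KO2 (adjusted p = 0.913), and their median was 0.07 in limma-voom. The medians were 0.05 and 0.07 for angiogenesis and hypoxia genes, -0.08 and -0.08 for the pentose phosphate pathway and 0.01 and 0.04 for stress response genes. Among the marker lists, early B lineage genes had medians of 0.17 and 0.09, mature B and plasma cell genes 0.31 and 0.18 and erythroid and megakaryocyte genes 0.44 and 0.30. The mature B list was called higher in DESeq2 without WT2 and KO2 (0.36, adjusted p = 0.0367), but not in edgeR without them (0.0828), nor there with an estimated correlation (adjusted p = 0.577). The median, the mean and the camera direction differed in sign for AP-1 genes (0.09, 0.05, down), adhesion receptors (0.08, -0.29, down), glycolysis genes (-0.08, 0.03, down) and the T and NK cell (-0.12, 0.30, down), myeloid (0.30, 0.76, down) and stem and progenitor (0.12, 0.22, down) markers. The stromal list and the sex-linked list, with 3 and 1 tested genes, were too short to test. Of 5 immunoglobulin variable segments with a row, 1 had any count, so the clones could not be compared by their rearranged segments.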

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

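The settings that leave out WT2, KO2 or both, other than leaving out each library in turn, were chosen after the data had been seen. edgeR and limma-voom called 0 genes, and 0 changed at least 2-fold, under every setting run. DESeq2 called 218 genes, 45 of them changed at least 2-fold. It called 277 and 69 without WT2, 684 and 165 without KO2, and 340 and 104 without both; the cause was not tested. The Cdk6 log2 fold change of 0.14 ran from -0.22 to 0.31 with a library left out. It turned negative, never past the threshold, without KO2 (-0.22, and -0.23 in DESeq2) and without WT2 and KO2 (-0.24, and -0.25 in DESeq2), since KO2 holds the highest value. With 5 lists called at first, leaving out a library called 5 to 7, leaving out WT2 and KO2 called 8 (8 in DESeq2), DESeq2 without WT2 called 8, and fry and the estimated correlation, with or without WT2 and KO2, called 0. The p53 list was lost without the low-count filter (adjusted p = 0.0549), without KO2 (0.068) and in DESeq2 without KO2 (0.0744) or without both (0.0515). Of the 29 lists 18 were called under no setting. The G2/M list had medians from -0.09 to 0.08 with a library left out, and its camera direction turned upward without WT2, KO1 or KO3. The fit with the replicate number as a block called 0 genes and 5 lists and put Cdk6 at 0.09, so the block changed no call. For 67 further genes named or followed, 127 of 1204 values under other settings passed the threshold, all of them in DESeq2, and 8 reversed. Cdkn2a, at -0.03, reversed with library totals (0.01), without KO2 in DESeq2 (0.56), without both in either tool (0.38) and over a range of -0.73 to 0.56 with a library left out. It was at -2.51 in limma-voom and -1.07 with the replicate block, where Cdkn2b went from -0.70 to -2.76 and -1.58; both genes have 1 count or none in KO2. Klrb1c, at 1.09, was at -0.03 without KO2 in DESeq2 and ran from -0.03 to 1.55 with a library left out. At the depth of these libraries 3 counts equal 0.168 CPM or less. The biological coefficient of variation was 36.3% over all libraries and 16.2% without WT2 and KO2. Without WT2 the WT group rests on WT1 and WT3, which correlated at 0.99, against 0.964 for KO1 and KO3. Since WT1 and WT3 are not shown to be separate cultures, fits without WT2 may understate the spread within WT.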

Other observations

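The tests of the mixture in WT2, of copy number, of the WT2 and KO2 libraries as a source of the list shifts and of class I paralogs were chosen after the results had been seen, as was counting DESeq2 calls over splits, and the edgeR counts over splits had been seen before their bounds were written. Genes that were silent in KO2 alone came from many chromosomes. At most 3 counts in KO2, against at least 10 CPM in each of WT1, WT3, KO1 and KO3, were found for 63 genes. Among them were Vopp1, at 107 to 125 CPM in those 4 libraries, Tlr7, a receptor for single-stranded RNA, at 40.3 to 65.9 CPM, Ryk, a Wnt receptor, at 84.4 to 93.3 CPM, and Ptk2, the focal adhesion kinase, at 55.4 to 61.2 CPM. Conversely 123 genes reached at least 5 CPM in KO2 and at least 20 times the highest of those 4 libraries. The highest of these was Col27a1, a fibrillar collagen, at 270.6 CPM in KO2, 65.9 CPM in WT2 and no more than 2.13 CPM in the other 4, followed by Cnn2, Tmem132e and Pcdh9. These genes were named after their values had been seen.

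By the median over genes, WT2 lay between KO2 and the other 4 libraries for both kinds of gene, though not for each gene: Tlr7 was at 47.8 CPM in WT2 and 40.3 CPM in KO3. Cells, RNA or reads of the KO2 library mixed into WT2 would raise the higher regions of chromosomes 6 and 13 in WT2 to a median log2 ratio of 0.23 (at least 0.21), given the share of 0.34 (0.31 to 0.38) read from the lower regions, and the median was 0.02 (0.00 to 0.05), which argues against that source. A candidate explanation is a related population within WT2 that shares the lower regions and silent genes of KO2 but not its raised regions: the share of the silent genes' expression missing in WT2, outside the regions, was 0.35 (0.33 to 0.39), as in the lower regions, and it was 0.34 for both Xist and Cdkn2a. The genes high in KO2 alone had a median of 0.24 of their KO2 level in WT2 (0.22 to 0.27; quartiles 0.16 and 0.31), below the share of 0.33 to 0.39. The related population sets no value for these genes and stays a hypothesis. No biological explanation by genotype was tested, since the pattern crosses the groups.

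The long regions in KO2 did not follow gene composition: after a trend over GC content and gene length had been taken out, the smallest of the 4 region medians was 0.58 in size. The median folds were 0.54 and 0.67 in the lower regions and 1.47 and 1.54 in the higher ones. A change in the number of copies stays open: at least 84% of the genes in each region lay on the side of its median, but the regions were chosen for that shift, and any shift of a whole region would look alike.

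By camera with the preset correlation, the calls of the lists other than p53 targets did not need libraries WT2 and KO2. All 4 were called in the same direction in edgeR and in DESeq2, each without KO2 and without both libraries. This does not tie them to genotype, since 6 of the 10 splits of the libraries, the real one included, called at least 5 lists. Without KO2 the medians of the interferon and class I lists went from 0.91 to 0.30 and from 0.57 to 0.29. Without both they were 0.36 and 0.51, and without WT2 alone 1.03 and 0.77. For the p53 list WT2 and KO2 stay open as the cause: its median went from 0.35 to 0.09 without KO2, and its adjusted p reached 0.0744 in DESeq2, while in edgeR without both libraries it was still called (0.15, adjusted p = 0.0354). All 5 lists were called after a trend over GC content, gene length and mean level, which held 17.5% of the variance of the gene statistics, had been taken out. The 12 class I genes outside the H2 family had a median of 0.43 and were called on their own (adjusted p = 0.000681), which argues against reads shared among paralogs as the whole cause. All these calls were made with the preset correlation. With an estimated one neither these 12 genes (adjusted p = 0.662) nor any full list was called. The size of the correlation is not the only reason for that loss. With an estimated correlation camera takes its degrees of freedom from the few libraries, with a preset one from the many genes. The estimated form thus has little power here, and a lost call does not by itself show that correlated members made it. For cytokine receptors the estimated value, -0.03, lay below the preset 0.01, yet the unadjusted camera p rose from 0.0552 to 0.101. For p53 targets it was 0.02, and the unadjusted camera p rose from 0.00139 to 0.0382. Differences between clones that have nothing to do with Cdk6 stay open, untested, as does the knockout.

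The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. edgeR called 0 genes in the real split, also at 2-fold or more, so counting splits with as many decides nothing there, and the highest of the others called 1. For lists 6 of the 10 splits, the real one included, called at least 5, and the highest other called 7, with WT1, WT3 and KO1 on a side. DESeq2 called 218 genes in the real split, 1 of 10 splits with as many, and at most 128 in the others. If the numbers are taken as pairing the libraries, which rests mainly on WT2 resembling KO2, 4 splits part all 3 pairs. The other 3 of these called at most 1 gene in DESeq2 and at most 5 lists, while the remaining splits set WT2 and KO2, or another pair, on one side. The main fit did not use this pairing, and 4 splits are too few to decide between the groupings.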
